A study of Mus musculus with 18 samples.

How the data were processed

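The samples are 18 pools of mammary tumour RNA, 1 per AKXD recombinant inbred strain crossed to a polyoma middle T transgenic line, per the labels. RNA was isolated from snap-frozen tumours with the mirVana kit and sequenced on an Illumina Genome Analyzer IIx, per the labels and the series' design text. How many tumours or mice entered each pool is not given in the sources used here.

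The deposited table holds 583 mature miRNA rows and 18 columns of log2 values with 2 decimals, and column names were matched to samples through the sample descriptions. BWA and the mm9 build are named without version or role per the submitters' processing notes. The counter, the miRNA annotation and any filter are not given in the sources used here. From the values themselves, 2 to the power of a deposited log2 value is a whole number of reads times 1 constant per library. This held for 100.0% of the 3818 values of up to 50 reads, within 0.006 log2. The constants lie between 0.999 (strain 25) and 1.39 (strain 7), and how the authors set them is not stated. No pseudocount was added, and a row without reads is written as 0. In strain 25, where the constant is 1, a single read is also written as 0. Because the deposited unit is log2 and not counts, the planned log2 CPM from a count model was replaced by the planned fallback, log2(CPM + 1).

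The log2 values were turned back to a linear scale, with 0 kept at 0. Of the rows, 20 fall in 8 sets with identical values in every library, and each set was counted once, which left 571 distinct rows. Libraries were scaled by a trimmed mean of M values (30% of log ratios and 5% of abundances trimmed), with factors between 0.671 (strain 14) and 1.67 (strain 28), and expressed as CPM. A pseudocount of 1 CPM was added before log2, which understates changes of low miRNAs. The 281 rows with a mean of at least 10 CPM were tested. The libraries held 4357636 to 14943355 reads, and the median SD from read counting over the tested miRNAs was 0.05 log2. Intervals and floors from reads cover counting error only, since PCR copies are not told apart.

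Groups are strains with n = 1, so no test between strains was run, and p-values describe the spread among these libraries. Which miRNAs vary more than others of like abundance was tested with limma 3.58.1 in R 4.3.3 (robust prior of variances, trended on mean log2 CPM). A list's coherence is the mean pairwise Spearman correlation of its members over the 18 strains, tested one-sided against 10000 independent permutations of each member, and compared with 10000 random lists matched on abundance. A list score is the mean over members of log2(CPM + 1) minus the member's panel mean. Pairs of list scores were tested with two-sided permutation tests of 100000 resamples. The test of 2 levels takes the largest ratio of between-range to within-range sums of squares with at least 4 strains on each side, against 10000 normal samples. Adjusted p-values are by Benjamini-Hochberg, with a threshold of 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.

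These tests, 31 lists, 16 pairs, the alternatives and the rule for named miRNAs were fixed before the data were examined. The rule takes the 10 most abundant miRNAs, the 10 with the largest SD, the 5 with the smallest SD at 100 CPM or more, the 5 with the smallest p for 2 levels, every measured member of the miR-290 cluster and the 2 to 4 most abundant members of each other list. The other arms of miR-21, miR-146b and let-7c, and the low testis-linked miRNAs, were named after their values were seen. Of the lists, 27 had at least 2 tested members. The liver list had 1, and the miR-290 cluster, H19/Igf2 and testis X cluster lists had none at 10 CPM. Matches to GENCODE genes of GRCm38 were made by name for 539 of the 583 rows; the authors' build is mm9, and the table has no coordinates.

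The tests were tried on simulated strains with the same abundances and depths. The variance test called 92.9% of 14 miRNAs with an SD raised 4 times when they were simulated alone, and 0 of 20 when they were mixed with 60 miRNAs of 2 levels and 6 lists sharing a factor. The first simulation was the mixed one, and the simulation with 14 alone was added after it had failed. The prior had 6.88 degrees of freedom in the simulation with 14 alone and 2.25 in the mixed one, against 3.57 in the data, so a count of 0 in the data is weak evidence. The test of 2 levels called 100% of 20 miRNAs with levels 3 log2 apart, 80% of 20 at 2 log2 and 10% of 20 at 1 log2, and 15.6% of its 45 calls were false, above the 5% aimed at. All of the 6 lists with a shared factor had p under 0.05, as had 7.5% of 200 lists without one.

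Alternatives were other scalings, filters and pseudocounts, each strain left out in turn, other correlation and score definitions, and other minimum numbers of strains per side. After the data had been seen, analyses without strains 10, 13, 14 and 20, without these and strain 28, with identical rows all counted, with each arm of miR-126 alone and with the first principal component removed were added. Those strains were chosen because they stood apart on the first principal component or in the values of 3 abundant miRNAs, not from any label.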

Results

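Small RNA was sequenced from mammary tumours of mice bred from 18 AKXD recombinant inbred strains. AKXD strains were derived from AKR/J and DBA/2J mice, so that each strain is fixed for the allele of either parent at most loci. Each strain was crossed to FVB/N mice that carry the polyoma virus middle T oncogene under the mouse mammary tumour virus promoter, and the F1 offspring develop mammary tumours. RNA of the tumours of a strain was pooled and sequenced as 1 library, so that every strain is a group with n = 1 and no difference between a pair of strains has a replicate check. The spread over the 18 libraries (SD, n = 18) holds strain, pool and library differences together. The libraries held 4357636 (strain 7) to 14943355 (strain 27) miRNA reads. The deposited log2 values were converted to CPM, and 281 mature miRNAs with a mean of at least 10 CPM were tested. CPM are reads scaled by the library total and by a factor per library, 0.671 in strain 14 to 1.67 in strain 28. A CPM value is therefore not a share of the reads of its library. Coordinates are those of GRCm38.

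The tumour libraries were dominated by let-7 miRNAs, miR-1 and miR-21. Averaged over the 18 strains, let-7c, a member of a family linked to differentiation, was at 182275 ± 67224 CPM (SD, n = 18). miR-1, a miRNA of skeletal and heart muscle, was at 97276 ± 68714 CPM, and miR-21, which is raised in many carcinomas, at 62322 ± 17742 CPM (65972 ± 8926 CPM over the 17 strains other than strain 28). let-7f, let-7b, let-7a, miR-148a, miR-30a, miR-146b and miR-378 completed the 10 most abundant, from 65095 CPM for let-7f to 33481 CPM for miR-378. let-7c took the largest share of reads in 15 strains, miR-1 in strains 14 (19.5% of reads) and 24 (15.6%), and miR-148a in strain 28 (8.02%).

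The panel was compared to find which miRNAs differ most among strains. The largest spread was that of miR-196a, a miRNA of the Hox gene clusters, with 411.96 CPM in strain 20 and 6.21 CPM in strain 22 (SD 2.35 log2, n = 18). miR-217 (SD 1.97), miR-216a (SD 1.69) and miR-216b (SD 1.49), which lie within 1 locus of chromosome 11, were also among the 10 most variable. miR-122, which is abundant in liver, went from 1.56 CPM in strain 21 to 375 CPM in strain 14 (SD 1.79). miR-150, a miRNA of mature lymphocytes, went from 4.53 CPM in strain 10 to 313 CPM in strain 27 (SD 1.55). The muscle miRNA miR-133a reached 714 CPM in strain 24 and 23.3 CPM in strain 10 (SD 1.37), and miR-9*, from the hairpin of the neural miRNA miR-9, 208 CPM in strain 9 and 3.17 CPM in strain 18 (SD 1.44). miR-709 (SD 1.45) and miR-21 (SD 1.87) completed the 10, miR-21 because of strain 28 alone, as described with that library. The steadiest miRNAs with at least 100 CPM were miR-17, miR-181b and miR-652 (each SD 0.21), miR-101b (SD 0.22) and miR-194 (SD 0.23). The median SD of the 281 miRNAs was 0.45 log2 (quartiles 0.34 and 0.61), 20 miRNAs had an SD of at least 1, and the SD exceeded 2 times that of read counting in 278. With limma's robust trended prior of variances, 0 miRNAs were called more variable than others of like abundance (13 at an unadjusted p under 0.05; smallest adjusted p 0.736; 0 without the robust option). The test had little room to call any: the prior had 3.57 degrees of freedom, a single call needed an SD 13.3 times the trend, and the largest, that of miR-196a, was 5.74 times the trend.

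**Figure D1:**
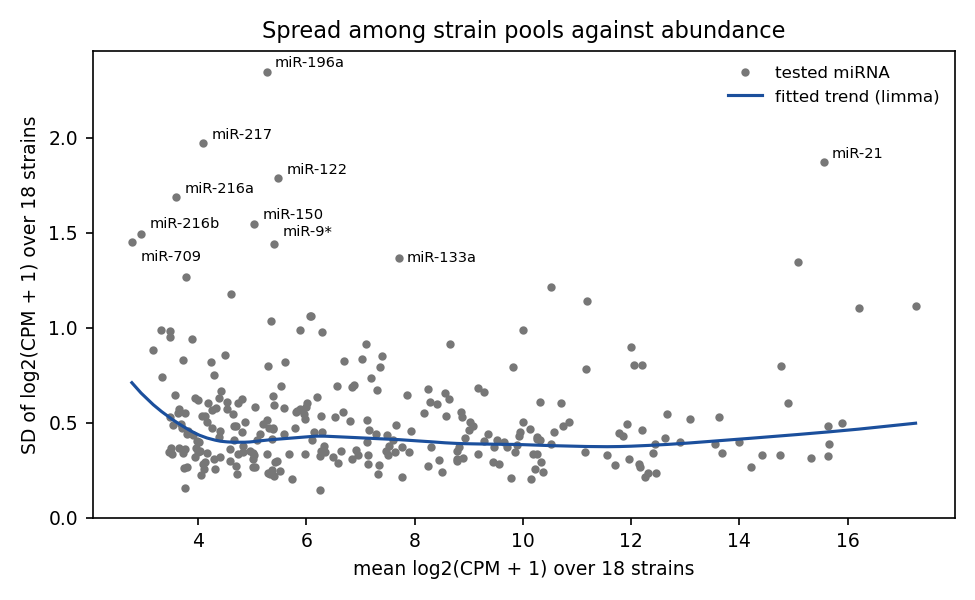
SD of log2(CPM + 1) over the 18 strain libraries against mean log2(CPM + 1), with 1 point per tested miRNA and limma's fitted trend as a line. The 10 largest SDs are named, and miR-196a lies highest at 2.35 log2.

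Each strain passes 1 of 2 parental alleles to its F1 offspring, beside a common FVB/N allele. A miRNA set by a single locus could then take 2 levels, and the test of 2 levels called 3 miRNAs. In simulated strains, where 60 of 281 miRNAs had 2 levels, 15.6% of 45 such calls were false. That share depends on how many miRNAs have 2 levels, so the error rate of these 3 calls is not known. No genotype was used here. miR-196a lay between 6.21 and 26.5 CPM in 12 strains and between 233 and 411.96 CPM in strains 2, 9, 13, 18, 20 and 27, with a gap of 3.09 log2 between the ranges. miR-216a lay at 5.20 CPM or less in 9 strains and at 27.0 to 55.3 CPM in strains 3, 10, 13, 14, 20, 21, 22, 23 and 28 (gap 2.18 log2). miR-217 lay at 7.72 CPM or less in 9 strains and at 40.6 to 155.4 CPM in the same 9 strains as the higher values of miR-216a (gap 2.25 log2). These strains were also the 9 highest for miR-216b, at 12.8 to 33.1 CPM against 5.93 CPM or less in the others (gap 0.99 log2). miR-216a and miR-217 are best known from the exocrine pancreas. Mir216b (chromosome 11, 28746191 to 28746276), Mir216a (28757012 to 28757083) and Mir217 (28763728 to 28763835) lie on the plus strand, the latter pair in an intron of the lincRNA Gm12082. miR-196a can come from Mir196a-1 (chromosome 11, 96265164 to 96265265, outside other genes) or Mir196a-2 (chromosome 15, 102973350 to 102973434, in an intron of Hoxc5), which the mature sequence does not tell apart. The ratio of between-range to within-range sums of squares was set against 10000 samples of 18 normal values, with Benjamini-Hochberg adjustment over the 281 miRNAs. miR-196a (ratio 17.1), miR-216a (17.1) and miR-217 (9.14) were called, each with adjusted p = 0.00937, from 1e-04, the smallest p that the 10000 samples can give. At an unadjusted p under 0.05 there were 20 miRNAs. miR-380-5p (adjusted p = 0.176) and miR-216b (adjusted p = 0.219) came next and were not called. The call of miR-217 was lost when any of strains 2, 7, 11, 13, 14, 20, 23, 25, 27 or 28 was left out, with ratios of 8.34 to 9.23, and that of miR-216b appeared without strain 9 (ratio 8.59), where 4 miRNAs were called, as without strain 24. With the first principal component of the libraries removed, 1 call was left: the ratio was 12.1 for miR-196a, 2.81 for miR-216a and 3.22 for miR-217. Without strains 10, 13, 14, 20 and 28 there were 0 calls among the 13 strains left, at ratios of 24.0 for miR-196a, which is higher than over all 18, 11.5 for miR-216a and 7.86 for miR-217, so the loss for miR-196a goes with fewer strains and not with a smaller split.

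**Figure D2:**
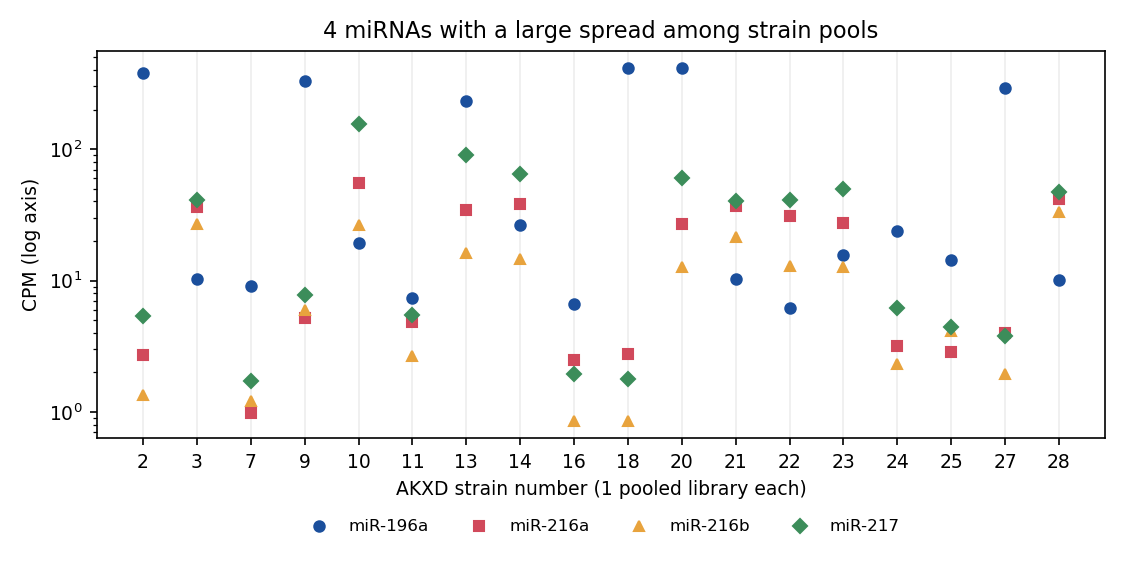
CPM on a log axis of miR-196a, miR-216a, miR-216b and miR-217 in each of the 18 strain libraries, 1 point per miRNA and strain. miR-196a lies at 233 to 411.96 CPM in 6 strains and at 6.21 to 26.5 CPM in 12, while miR-216a, miR-216b and miR-217 are highest in the same 9 strains.

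Lists of miRNAs known from other cell types were compared across the tumour pools. Among lists with at least 2 tested members, the skeletal muscle score varied most (SD 1.05 log2, n = 18): miR-1, miR-206, miR-133a, miR-133b and miR-133a* had a mean pairwise Spearman correlation of 0.758, and the list score ran from -1.84 log2 in strain 10 to 1.55 in strain 14. Both of these strains are low on the first principal component. By the summed CPM of its 6 measured rows the list was lowest in strain 9 (22483 CPM) and highest in strain 14 (303127 CPM). miR-1 was at 21591 CPM in strain 9 and 290908 CPM in strain 14, and miR-206 at 743.2 CPM in strain 28 and 11667.5 CPM in strain 14. The leukocyte list (mean correlation 0.610) was highest in strain 27, where miR-142-3p reached 17101 CPM and miR-155 226 CPM. It was lowest in strain 10, where miR-142-3p was at 1361 CPM, followed by strains 13 and 20 (scores of -1.16, -0.655 and -0.651). All 3 are low on the first principal component, but strain 14, which is low on it too, had a leukocyte score of 1.06. The erythroid list of miR-451, miR-486 and miR-144 (0.680) was highest in strain 14 and lowest in strain 9, with miR-486 at 311 and 36.2 CPM. miR-203 and miR-205, miRNAs of stratified and basal epithelium, rose and fell together (0.7503), and miR-203 reached 9932 CPM in strain 2 against 993 CPM in strain 22. All of these lists passed the permutation test of coherence over 27 lists (adjusted p = 0.00027 for muscle, leukocyte and erythroid, from 1e-04, the smallest p that the permutations can give, and 0.000579 for basal epithelium). The miR-199/miR-214 list of mesenchymal miRNAs was coherent too (0.302, adjusted p = 0.00612). The genes of miR-206 and miR-133b, of miR-144 and miR-451, and of miR-1 and miR-133a are neighbours on 1 strand. The muscle, leukocyte and mesenchymal lists also hold both arms of a hairpin. Coherence of such members can come from a shared transcript, so it is no measure of cell content alone. By contrast, miR-203 and miR-205 lie on chromosomes 12 and 1. miR-143 with both arms of the miR-145 hairpin (0.115, adjusted p = 0.271), both arms of miR-126, an endothelial miRNA (-0.0299, adjusted p = 0.678), miR-192, miR-194 and miR-215 of gut and kidney epithelium (-0.0850, adjusted p = 0.774), and miR-9, miR-9* and miR-128 of neural tissue (-0.122, adjusted p = 0.833) did not pass. With the first principal component removed miR-143 with the miR-145 arms was called (0.418). With total counts alone that list (0.291) and miR-192, miR-194 and miR-215 (0.614) were called. miR-122, the only miRNA of the liver list, had no partner to be tested with. The libraries of strains 10, 13, 14 and 20 stood lowest on the first principal component (27.6% of the variance), and the miR-126 arms were called coherent without them and strain 28 (0.577), with that component removed (0.752) and with total counts alone (0.420).

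**Figure D3:**
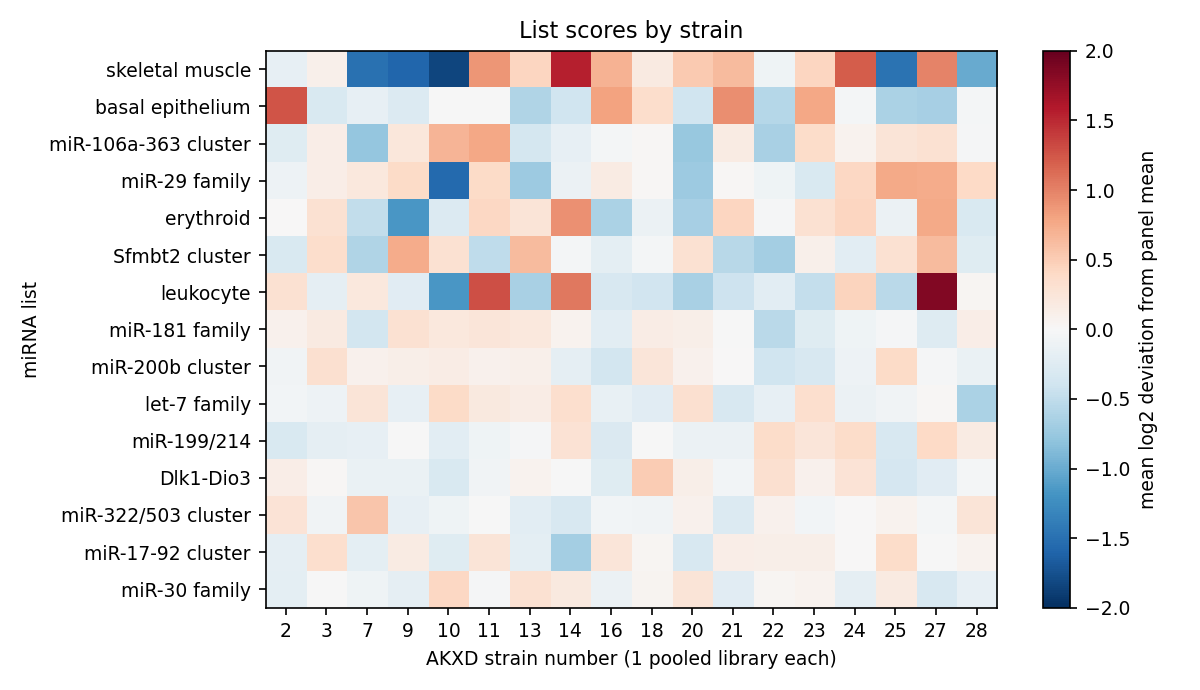
Scores of the 15 coherent miRNA lists (rows, by falling mean correlation) in the 18 strain libraries (columns), as the mean log2 deviation of the members from their panel means. The skeletal muscle score runs from -1.84 in strain 10 to 1.55 in strain 14, and the leukocyte score is highest in strain 27 at 1.85.

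miRNAs that share a primary transcript or a family varied together in 10 further lists. The X-linked miR-106a-363 cluster was the most coherent of the clusters (miR-20b, miR-363 and miR-106a, mean correlation 0.728), with miR-20b at 117 CPM in strain 11 and 31.9 CPM in strain 20. The miR-29 family (0.705) was lowest in strain 10, where miR-29a was at 714 CPM and miR-29b at 96.3 CPM, and highest in strain 25, at 2622 and 555 CPM. Its 3 lowest scores, in strains 10, 13 and 20 (-1.55, -0.73 and -0.73), are those of libraries that stand apart on the first principal component. Strain 14, which also stands apart on it, had a score of -0.11. The Sfmbt2 cluster (0.673), a large set of near-identical miRNAs in an intron of Sfmbt2, was highest in strain 9 and lowest in strain 22. The epithelial miR-200b cluster (0.321) ran from -0.40 in strain 22 to 0.39 in strain 25, and the imprinted Dlk1-Dio3 cluster, with 19 tested miRNAs such as miR-379, miR-541 and miR-127 (0.283), was highest in strain 18. The miR-181 family (0.391), let-7 family (0.306), miR-322/miR-503 cluster (0.259), miR-17-92 cluster (0.216) and miR-30 family (0.187) also passed, with adjusted p of 0.000415 or less. The call of the miR-30 family was lost without strains 10, 13, 14, 20 and 28 (0.0788) and with the arms of a stem summed (0.111), and that of the miR-322/miR-503 cluster at a mean of 100 CPM or more, where its sign turned (-0.0031). The miR-30 family lay above 93.8% of random lists matched on abundance, and the other 14 coherent lists above at least 96.8%. Reads can be shared between near-identical members of the let-7, miR-29, miR-30 and miR-181 families, the miR-17-92 and miR-106a-363 clusters and the Sfmbt2 cluster, so their coherence is uncertain to that extent. No coherence was called for the miR-106b-25 cluster (-0.0175, adjusted p = 0.678), miR-183 cluster (0.0901, adjusted p = 0.271), miR-200c cluster (0.160, adjusted p = 0.200), miR-34 family (-0.300, adjusted p = 0.890), miR-15/16 family (0.0866, adjusted p = 0.157), miR-23/27/24 (0.0517, adjusted p = 0.170) or miR-221/miR-222 (-0.139, adjusted p = 0.774). The miR-183 cluster was called without strains 10, 13, 14 and 20 (0.441), without these and strain 28 (0.468) and with the first principal component removed (0.661). The miR-200c cluster was called without the 5 strains (0.332) and with arms summed (0.709), the miR-15/16 family in 6 alternatives besides total counts (0.150 to 0.253), and miR-23/27/24 under upper-quartile scaling (0.0859). With libraries scaled by total counts alone, 24 lists were coherent in place of 15.

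Scores of 13 pairs of lists were then correlated across the 18 strains. The scores of the epithelial miR-200b and miR-200c clusters, which lie on chromosomes 4 and 6, rose and fell together: Pearson r was 0.707 (permutation p = 0.00111) and Spearman rho 0.767 (permutation p = 0.00047, adjusted over the 13 pairs p = 0.00611). In the main setting the miR-200c list was not coherent (0.160, adjusted p = 0.200 in the test of coherence), so its score is an uncertain measure of that cluster. Sharing of reads between members of the 2 clusters was not tested. Without strains 22 and 16, farthest from the median of the miR-200b score, r was 0.635. The leukocyte score rose with the mean of the 2 arms of miR-126 (r = 0.839, permutation p = 6e-05; rho = 0.713, permutation p = 0.00129, adjusted p = 0.00838), and r was 0.716 without strains 27 and 11. As these arms were not coherent over all 18 strains in the main setting, each was then taken alone, which was chosen after the data had been seen: miR-126-5p gave r = 0.825 (permutation p = 5e-05; 0.735 without strains 27 and 11) and rho = 0.835, and miR-126-3p, the more abundant arm, r = 0.340 (permutation p = 0.167; 0.157 without them) and rho = 0.123 (adjusted p = 0.625). Over all 18 strains the relation was called for 1 arm only, and whether it reflects endothelium is left open. The miR-200b relation lost its call without strains 10, 13, 14 and 20 (rho = 0.582), without these and strain 28 (rho = 0.709) and with identical rows all counted (rho = 0.595), the leukocyte relation lost it under upper-quartile scaling (rho = 0.595), and both lost it when members were summed before the log (rho = 0.395 and 0.0898). For the other 11 pairs the adjusted p of rho was 0.103 or more, among them the miR-17-92 cluster with the let-7 family (r = -0.523, rho = -0.523, adjusted p = 0.103) and the miR-200b cluster with miR-199/miR-214 (r = -0.511, rho = -0.467, adjusted p = 0.103). The former was called without strain 11 (rho = -0.618), under median-of-ratios scaling (rho = -0.614) and at a mean of 100 CPM or more (rho = -0.707), and the latter without strain 16 (rho = -0.625). With total counts alone both were called in the opposite direction (rho = 0.525 and 0.546). The erythroid score with the miR-126 score was called by Pearson r (r = 0.618, adjusted p = 0.0273, against rho = 0.465), and the miR-17-92 with the miR-106b-25 cluster (rho = 0.315) at a mean of 100 CPM or more (rho = 0.705) and with no filter (rho = 0.614). With total counts alone these 2 pairs were called too, as were erythroid with leukocyte and miR-199/miR-214 with miR-143/miR-145 and with Dlk1-Dio3. No batch is given in the labels, so no value within batches can be given.

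A list of 9 miRNA stems studied in metastasis, with 13 tested miRNAs, was not called in the test of coherence (mean correlation -0.0120, adjusted p = 0.737). With total counts alone it was called (0.0888). No measure of metastasis is in the labels, so the list was not related to one. Of its members, miR-9 went from 301 CPM in strain 18 to 8296 CPM in strain 9 (SD 1.21 log2), and miR-126-3p was at 12442.5 ± 3470 CPM (SD, n = 18). miR-206 is also a member of the skeletal muscle list and is described with it. Over the 17 strains other than strain 28, miR-21 had an SD of 0.20 log2 and miR-146b one of 0.37. There miR-21 (Mir21a, chromosome 11, 86584067 to 86584158, in an exon of Vmp1) was at 274 CPM from 2537 reads, 256-fold below the median of 70033 CPM in the other 17 strains, which ranged from 52905 to 79673 CPM. miR-146b was 41.1-fold lower in strain 28, at 941 CPM, and let-7c 19.3-fold lower, at 8645 CPM. The other arms of these hairpins were not low in the same library: miR-21* was at 115 CPM against a median of 57.1 CPM, miR-146b* at 46.1 against 38.3 CPM and let-7c-1* at 2.37 against 1.97 CPM. With strain 28 included, the SD of miR-21 was 1.87 log2. Strain 28 was examined after its values had been seen.

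**Figure D4:**
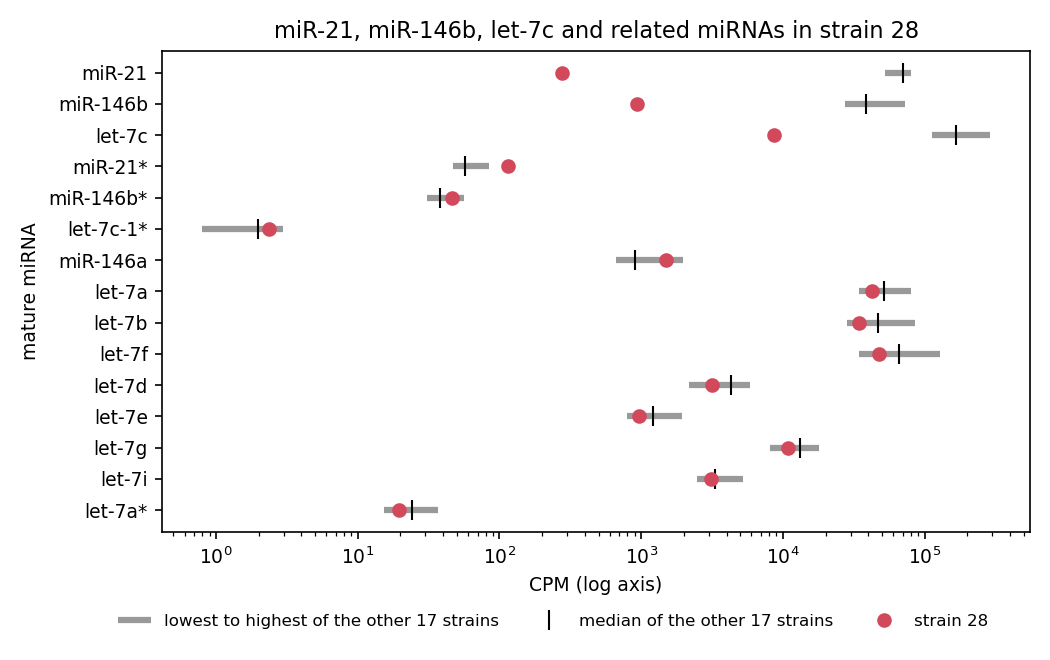
CPM on a log axis of miR-21, miR-146b, let-7c, their other arms and related miRNAs in strain 28 (red points), with the range (grey bars) and median (black ticks) of the other 17 strains. In strain 28 miR-21, miR-146b and let-7c lie at 274, 941 and 8645 CPM, below the lowest of the other strains, and the other miRNAs do not.

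The miR-290 cluster, which marks pluripotent cells, was close to the limit of detection. Its 3 measured miRNAs, miR-291a-3p, miR-291a-5p and miR-295, had 35 reads in all over the 18 libraries and were listed at 0 in 6 of them, among them strain 25, where a single read per row is also written as 0. A count of 0 allows up to 3 reads, or 0.193 CPM in the deepest library and 0.733 CPM in the shallowest, for counting error only. The 3 planned pairs of this cluster with other lists had no score to correlate. miR-483 and miR-675-3p, from the imprinted H19/Igf2 region, had 17 reads in all, with at most 3 in a library. Both lists fell below 10 CPM and were not tested in the main setting. With no filter neither was coherent (miR-290 cluster 0.165, adjusted p = 0.204; H19/Igf2 -0.245, adjusted p = 1), from counts too low to show that strains are alike.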

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

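Results here are sums of reads in lists with no member at 10 CPM, outside the comparisons of the main setting, where a library exceeded the 3 reads that a count of 0 allows; this limit was set for these lists after the reads had been seen.

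The testis-linked miRNAs of the X chromosome, among them miR-470, miR-741, miR-743a, miR-878-5p, miR-880 and miR-881, had 455 reads over 17 rows in strain 2. The median was 11.5 reads over the 18 libraries, with 1 read in strain 7. Scaled to the library, strain 2 had 36.2 CPM, strain 23 had 35.2 CPM, strain 16 had 22.2 CPM and strain 21 had 8.82 CPM, against a median of 1.29 CPM. In the alternatives with a lower filter these miRNAs varied together: the mean correlation was 0.539 for the 2 at 1 CPM or more (adjusted p = 0.0206) and 0.604 for all 17 (adjusted p = 0.000273). The miR-290 cluster had 7 reads in strain 27, or 0.45 CPM, its largest number of reads in a library, and 5 reads in strain 16, where its CPM was highest (0.538). No explanation was tested for either.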

How the results depend on the processing

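The settings without named strains, with 1 arm of miR-126, with identical rows all counted and with the first principal component removed were chosen after the data had been seen. The count of more variable miRNAs stayed at 0 under all alternatives run. Leaving out each strain in turn gave 15 coherent lists throughout, 2 to 3 correlated pairs, 2 to 4 miRNAs of 2 levels and a median SD of 0.42 to 0.46. Of the main counts, scaling by total counts alone moved coherent lists from 15 to 24, correlated pairs from 2 to 9 and the median SD from 0.45 to 0.55. Coherent lists numbered 12 at 100 CPM, where 4 of the 15 were not called (3 of these had fewer than 2 members left), 17 under upper-quartile scaling and without strains 10, 13, 14 and 20, 18 without these and strain 28, 19 with the first principal component removed, 16 at 1 CPM, with no filter and with arms summed, and 15 in the others. Pairs numbered 1 under upper-quartile scaling, 4 at a mean of 100 CPM or more, 1 without strains 10, 13, 14 and 20, 1 without these and strain 28, 1 with identical rows all counted, 1 with miR-126-3p alone for endothelium and 0 with members summed before the log. miRNAs of 2 levels numbered 7 at 1 CPM, 1 at 100 CPM, which keeps 139 miRNAs and neither miR-216a nor miR-217, 16 with no filter, 0 without strains 10, 13, 14, 20 and 28 (13 strains are left, and the ratio of miR-196a is 24.0 against 17.1 over all, that of miR-216a 11.5 and that of miR-217 7.86) and 1 with the first principal component removed. The median SD was 0.37 with no filter, 0.38 without strains 10, 13, 14 and 20, 0.39 without these and strain 28 and 0.35 with the component removed. Signs turned in lists or pairs not called in the main setting, except for the miR-322/miR-503 cluster. With total counts alone calls were made at a mean correlation of 0.449 for the miR-106b-25 cluster, 0.420 for endothelium, 0.614 for gut and kidney epithelium and 0.0888 for the metastasis-associated list, and at a rho of 0.546 for the miR-200b cluster with miR-199/miR-214 and 0.525 for the miR-17-92 cluster with the let-7 family. Endothelium was called at 0.577 without strains 10, 13, 14, 20 and 28 and at 0.752 with the component removed, and the miR-322/miR-503 cluster lost its call at 100 CPM (-0.0031). Except for the filter at 100 CPM, the cause was not tested. The planned variance-stabilised alternative was not run. It takes counts, which the deposited log2 values are not, although reads could be worked back from them to within rounding. No other splits of samples apply, since every group has 1 library. No paired analysis was possible because each strain has 1 library. Depth limits miRNAs below 10 CPM: 1 read is 0.0643 CPM in strain 27 and 0.244 CPM in strain 7.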

Other observations

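The tests of strain 28, of 2 levels, of depth, top share, composition and scaling, and of neighbouring genes were chosen after the results had been seen, and only the test of hairpin GC content was set before.

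Some miRNAs stood high in 1 or a few strains. miR-34c, which p53 induces, was at 2395 CPM in strain 23 and 355 CPM in strain 27. miR-378, from an intron of Ppargc1b, a regulator of oxidative metabolism, was at 126625 CPM in strain 14 and 14415 CPM in strain 7. Within the epithelial and sensory miR-183 cluster, miR-183 was at 18305 CPM in strain 10 and 4015 CPM in strain 16, while the score of the cluster, which was not coherent, was 0.09 in strain 10, highest in strain 25 (0.68) and lowest in strain 14 (-0.76).

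miR-21, miR-146b and let-7c were 256-fold, 41.1-fold and 19.3-fold lower in strain 28 than the median of the other strains. Lower expression of Mir21a and Mir146b would lower both arms, but miR-21* and miR-146b* deviated by a median of 0.60 log2 from the panel in that library (SDs of 0.26 and 0.23 log2 over the other strains), while for let-7c, which has 2 genes, lower expression stays open, since let-7c-1* (0.18 log2, 22 reads) stands for 1 gene and the other arm of the second has no values apart from those of let-7a*. Another tissue would move many abundant miRNAs, and 3 of the other 47 among the 50 most abundant lay more than 1 log2 unit from their median, against a median of 3 and a highest number of 9 in the other libraries. Loss of the reads of single mature sequences in this library stays open: it would leave the other arms as they are, but miR-21* lay 3.76 SDs above its median and the other 2 arms did not stand out. A strain difference in processing of the arms stays open and untested.

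miR-196a, miR-216a and miR-217 were called as having 2 levels, and a shared axis of the libraries was weighed against an effect at the locus. After the first principal component was removed, the adjusted p of miR-196a was 0.0281 (gap 2.01 log2, from 3.09), so the axis is not its whole cause. An adjusted p from the smallest p of this test depends on how many miRNAs reach it. The rise from 0.00937 is therefore no measure of weaker evidence. For miR-216a and miR-217 the adjusted p rose to 1 and 1, and the gap fell from 2.18 to 0.62 and from 2.25 to 0.65 log2. The component is itself computed from these miRNAs, and miR-217 has its largest loading in absolute value (-0.245, with miR-216a at -0.162). Removing the component takes out part of their own levels, so this fall cannot tell the axis from an effect at the locus. Without strains 10, 13, 14 and 20, at unchanged scaling, miR-216a kept its call (adjusted p 0.014) and miR-217 did not (0.0562). The ratio of miR-217 was 9.99 against 9.14 over all strains, so its call ended with fewer strains. Both loadings are negative, so the axis would put high levels at low values of the component. In that direction, strains 3 and 23 were high at 1.12 and -2.54, and the low strains 7, 11, 16, 18, 25 and 27 lay at 2.27 to 6.69. However, strains 21, 22 and 28 were high at 3.01 to 5.41, and strains 2, 9 and 24 low at -0.315 to 1.35. The latter values argue against the axis alone setting the 2 levels of miR-216a and miR-217, and a part of it stays open. The third miRNA of the locus, miR-216b, shared all 9 highest strains with both, a larger number than in 100% of the 278 other miRNAs (at most 7), but this overlap had been seen before it was tested, so 1 cause acting on the locus stays open; parental genotypes, which could make it biological, were not used here.

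The first principal component held 27.6% of the variance, with strain 10 at -13.0 and strains 13, 14 and 20 at -8.55 to -7.04, against -2.54 or more in the others. Hairpin GC content does not account for it, since loadings had a Spearman correlation of 0.146 with it over 261 miRNAs, which are not independent replicates. Both arms of a hairpin were given its GC content, so a bias from the GC content of the mature sequences was not tested. The factors used for scaling are not its cause, since with total counts alone the same 4 strains were lowest and the component held 38.8%. As these 4 stand apart, no correlation over all 18 strains is given, although such values were computed, and over the other 14 the component had a rho of -0.596 with reads (permutation p = 0.0272, adjusted over 3 relations p = 0.0816; r = -0.575, permutation p = 0.0306, and -0.700 without the 2 farthest strains), 0.0857 with the share of the 3 most abundant miRNAs (adjusted p = 0.775; r = -0.138, permutation p = 0.634, and 0.116) and 0.442 with the scaling factor (adjusted p = 0.173; r = 0.511, permutation p = 0.0677, and 0.565). The composition of the libraries and a few miRNAs taking most of the reads stay open with strain differences. The 4 strains have the 4 lowest scaling factors (0.671 to 0.776, against 0.850 or more). Of them, 1 has a larger share of the 3 most abundant miRNAs (44.4%) than any of the 14. The bounds set for depth were not reached, and depth stays open for the order among the 14. However, 0 of the 4 lay outside the depths of the 14, and strains 24, 25 and 27, as deep, stood at 1.35 to 2.44. These values argue against depth alone setting the 4 apart.

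A hypothesis of shared primary transcripts was tested on all miRNAs with a single locus in GRCm38. The 207 pairs on the same strand within 50 kb had a median Spearman correlation of 0.309 across strains, without the 51 pairs of 2 arms of 1 hairpin (median 0.321). They form 25 groups of neighbours, of which the largest alone holds 77 pairs. The median of the group medians was 0.220, and 21 groups had a median above 0. As pairs share members, hairpins were shuffled among the loci, which gave a highest median over the pairs of 0.189 in 10000 shuffles. Most of these pairs belong to lists whose coherence had been seen, and the 30 pairs in no list together, from 5 groups, had a median of 0.195, which a share of 0.0293 of the shuffles reached (highest 0.451), too few groups to decide, so shared primary transcripts stay open as an explanation; near-identical copies that share reads are among the neighbours. A rho of miR-196a with other miRNAs of the Hox clusters was computed and is not given, because the values of miR-196a fall in 2 separate ranges; the relation was left untested.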
